A study of Mus musculus with 12 samples.

How the data were processed

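Bulk RNA sequencing of 12 mouse tumours was analysed: 4 from vehicle-treated mice, 4 from mice given palbociclib and mirdametinib and harvested during regression, and 4 from mice given the same drugs and harvested at the terminal time point. Per the labels, RNA was purified with the RNeasy mini kit and libraries were prepared with the TruSeq stranded mRNA kit. The deposited values are raw counts, 1 whole number per Ensembl gene for 54532 genes in each library. The authors' notes name HISAT2 2.2.1, Salmon without a version and DESeq2 1.24.0 with the builds mm10 and GRCm38.p6, without saying which tool counted the reads, on which strand, or against which annotation release. Overlapping genes and close paralogs can therefore share reads in ways that are not stated. Gene symbols and positions were taken from GENCODE M21 (GRCm38), in which 54495 of the identifiers were found. Totals ran from 13194699 to 22639625 reads. The count limits for a value of 0 were set at 3 counts and the 95% intervals for shares are Wilson intervals; both cover counting error only, since the reads carry no molecular identifiers.

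Groups were read from the treatment and harvest labels. The title ending FFT, carried by 2 vehicle, 1 regressing and 1 terminal combination library, is not explained in the sources used here and was treated as a possible batch. No 2 libraries were duplicates: the lowest chi-square per degree of freedom between any pair was 56.8. The tools were R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

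Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 15650. Counts were normalised by TMM and tested with the edgeR quasi-likelihood model fitted to all 12 libraries, for 3 contrasts and for any difference among the 3 groups. P-values were adjusted by the Benjamini-Hochberg method over all genes tested in a contrast, with a threshold of 0.05. The standard error of a log2 difference was taken from its size and the F statistic. CPM, the usual depth-adjusted counts, were computed with the TMM-adjusted library size and are given as mean ± SD over the 4 tumours of a group. The share of reads given for immunoglobulin covers all constant, variable, joining and diversity genes. Fold changes fitted for genes near a count of 0 depend on a prior count, so only CPM are given for those.

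Gene lists were written before the data were examined, 27 in all with 386 symbols, of which 348 were tested: plasma cell markers, immunoglobulin constant genes, B cell markers, T cell markers, cytotoxic lymphocyte genes, macrophage, dendritic cell, neutrophil and mast cell markers, antigen presentation, interferon response, lymphoid chemokines and B cell survival factors, immune checkpoint genes, E2F targets of the G1 to S transition, G2 and mitosis genes, MEK-ERK output genes, CDK4/6-RB pathway components, senescence-associated secretory genes, receptor tyrosine kinases and ligands, Schwann lineage genes, extracellular matrix and fibroblast genes, endothelial markers, skeletal muscle, adipocyte, keratinocyte and red blood cell genes, and hypoxia and glycolysis genes. Some genes are on more than 1 list. Each was tested against all other genes with limma camera on voom values at a preset inter-gene correlation of 0.01, adjusted by Benjamini-Hochberg over 81 tests. Camera assumes a small correlation between genes of a list, and none of the calls in any comparison held when the correlation was estimated from the data. By fry, which asks whether a list's genes move on balance one way, no list was called either. A list score is the mean log2 CPM of its members in a library with a prior count of 2. Scores were compared by exact two-sided permutation of 4 against 4 libraries (70 arrangements, smallest possible p 0.0286), and none passed after adjustment, with 3, 1 and 2 lists under 0.05 unadjusted in the 3 comparisons. Where a count is given as adjusted over the list alone, Benjamini-Hochberg was applied to the members of that list.

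The genes named were set by a rule written before the data were examined: where no gene passed, the 5 with the smallest p in each comparison, up to 4 members of each list described, those with the smallest p, and Nf1, Cdkn2a, Cdk4, Cdk6, Ccnd1, Map2k1, Map2k2, Rb1, Mki67, Dusp6, Spry4, Etv4, Jchain, Mzb1, Igkc, Cxcl13 and Cd274. Some genes that meet this rule are not reported here. Any gene outside the rule is said to have been chosen after its value was seen.

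The steps were tested on simulated data with the depth and spread of all 12 libraries, in 3 draws with 200 changed genes each. The changes were placed in the regressing group and tested against vehicle. EdgeR recovered 14.9%, 64.7% and 80.3% of genes changed 2-fold, 4-fold and 8-fold and called 14 unchanged genes, while DESeq2 recovered 37.3%, 80.6% and 91.9% and called 161. A shifted list of 10 genes was called in 3 of 3 draws and 0 of 78 unshifted lists were. Genes were drawn independently, whereas the estimated correlation of the mitosis list was 0.856 in regressing against vehicle tumours. The draws therefore do not show how often lists of correlated genes are called wrongly. The median biological coefficient of variation across genes was 0.339.

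Alternatives were RLE normalization, no filter beyond 1 read in any library, DESeq2, limma voom with sample quality weights, a fit to the 8 libraries of the groups compared, the FFT ending as a covariate, the 8 libraries without that ending, leaving out immunoglobulin genes or the muscle, keratinocyte, adipocyte and red blood cell genes, a minimum log2 change of 1, a prior count of 0.5 and the median of members for scores, and leaving out each library in turn. The correlation between the contrasts that share vehicle libraries was set against 100 simulations with no treatment effect and against splits of the vehicle libraries. Chosen after the data were seen were leaving out regressing replicates 1 and 4 together, and the muscle or adipocyte score as a covariate. In the closing section, 35 splits of the 8 libraries of each comparison and 100 of all 12 were counted. The labels give no link between animals of different groups, so no pairs were formed.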

Results

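RNA sequencing was done on 12 malignant peripheral nerve sheath tumours, aggressive sarcomas of the nerve sheath, in mice. The tumours were induced by adenoviral delivery of Cas9 directed at Nf1 and at a gene the labels spell Cdk2na, read here as Cdkn2a. The 3 groups held 4 tumours each. Vehicle tumours were harvested at the terminal time point. The other groups came from mice given 100 mg/kg palbociclib, a CDK4/6 inhibitor, with 1 mg/kg mirdametinib, a MEK inhibitor, each day by oral gavage: regressing tumours were harvested during regression, and terminal combination tumours at the terminal time point. The series design speaks of vehicle, combination-sensitive and combination-resistant tumours, and no label says which treated group is which. Replicates 1 to 4 held 22639625, 14181703, 18269791 and 16401245 counted reads in the vehicle group, 17527201, 17089999, 21935527 and 13194699 in the regressing group and 19804633, 18300425, 19164759 and 17926102 in the terminal combination group. A count of 0 in a library allowed up to 0.133 to 0.227 CPM, the depth-adjusted count unit used throughout, for counting error only. The labels do not say that the tumours came from separate mice, so the p-values measure the spread between these samples. Harvest stage differs between the regressing group and the others, so it cannot be separated from tumour state.

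The targeted genes were both transcribed in every library. Nf1 (ENSMUSG00000020716, chromosome 11, 79339693 to 79581612, GRCm38), which encodes the RAS regulator neurofibromin, stood at 17.92, 10.22, 22.06 and 21.82 CPM in vehicle replicates 1 to 4. It stood at 17.01, 12.54, 11.58 and 19.52 CPM in regressing replicates 1 to 4 and at 23.8, 13.82, 17.5 and 12.15 CPM in terminal combination replicates 1 to 4. Cdkn2a (ENSMUSG00000044303, chromosome 4, 89274471 to 89294653), which encodes the cell cycle inhibitors p16 and p19, varied far more within groups. Its values were 217.2, 244.2, 5.084 and 112.6 CPM in the vehicle tumours, 393.2, 7.49, 227 and 96.57 CPM in the regressing tumours, and 21.19, 257.3, 125.1 and 24.76 CPM in the terminal combination tumours. Counts over a whole gene do not show whether it was edited. Neither gene differed between groups in edgeR, with adjusted p of 0.748 and 0.921 for regressing against vehicle, 0.973 and 0.97 for terminal combination against vehicle, and 0.93 and 0.911 between the treated groups.

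The first comparison, regressing against vehicle tumours, asks how tumours shrinking under CDK4/6 and MEK inhibition differ from untreated tumours. By camera at a preset correlation, immunoglobulin constant genes were higher in the regressing tumours and genes of G2 and mitosis lower. Neither call held with an estimated correlation (adjusted p = 0.385 and 0.542). The immunoglobulin list, the constant regions of antibody heavy and light chains, had a mean log2 CPM score of 3.69 ± 1.51 (SD, n = 4) in regressing and 0.47 ± 1.02 in vehicle tumours. The mitosis list score was 5.24 ± 0.65 against 6.16 ± 0.25. Skeletal muscle and adipocyte genes were called higher in the same tumours, with scores of 9.85 ± 1.68 against 6.76 ± 1.77 for muscle and 4.23 ± 1.06 against 0.54 ± 1.53 for adipocyte genes. Those calls did not hold with an estimated correlation either (adjusted p = 0.409 and 0.385). No single gene passed at an adjusted p under 0.05 in edgeR, where 1986 genes had an unadjusted p under 0.05 and 782 would be expected by chance. DESeq2 called 483 genes, 344 higher and 139 lower. In the simulated data DESeq2 called 161 unchanged genes over 3 draws and edgeR 14, so DESeq2 calls here and below may include more false ones.

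Among immunoglobulin genes, Igkc (ENSMUSG00000076609, chromosome 6, 70726435 to 70726966), the kappa light chain constant gene, was at 511 ± 342 CPM (SD, n = 4) in regressing and 25.3 ± 37.7 CPM in vehicle tumours, a log2 difference of 4.34 (SE 1.1) with an edgeR adjusted p of 0.247. Ighm (ENSMUSG00000076617, chromosome 12, 113418558 to 113422730), the IgM heavy chain constant gene, was at 447 ± 280 against 68.5 ± 37.9 CPM. Ighg1, the IgG1 heavy chain gene, was at 3.76 ± 2 against 0.128 ± 0.131 CPM, Iglc1 at 6.48 ± 4.59 against 0.183 ± 0.195 CPM and Iglc2 at 4.72 ± 3.35 against 0.116 ± 0.0959 CPM. The lambda constant genes are close copies, so reads may have been shared among them. All 10 tested members were higher in the regressing group, and 9 passed when adjusted over the list alone. Camera called the list higher (adjusted p = 5.93e-08), and the call did not hold with an estimated correlation (adjusted p = 0.385 with an estimated correlation). The number passing over the list alone was 5 without vehicle replicate 1, 2 or 3 or without regressing replicate 4. All immunoglobulin genes, constant and variable, made up 0.125% ± 0.0828 of reads in regressing and 0.0129% ± 0.0113 in vehicle tumours (exact two-sided permutation p = 0.0571, adjusted p = 0.0856). Regressing replicate 3 was lowest of its group at 0.0238% (95% Wilson interval 0.0232 to 0.0245), under vehicle replicate 4 at 0.0292% (0.0284 to 0.03). DESeq2 called 11 immunoglobulin genes, all higher.

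Plasma cell markers, genes of antibody-secreting cells, were not called as a list. Its score was 3.74 ± 0.56 (SD, n = 4) in regressing and 2.94 ± 0.19 in vehicle tumours, with 11 of 14 tested members higher (camera adjusted p = 0.195). Jchain (ENSMUSG00000067149, chromosome 5, 88519809 to 88527891), which joins IgM and IgA into polymers, was at 53.4 ± 41.5 against 3.28 ± 4.33 CPM, a log2 difference of 4.03 (SE 1.1). Mzb1 (ENSMUSG00000024353, chromosome 18, 35647267 to 35649367), an endoplasmic reticulum protein of B and plasma cells, was at 4.81 ± 5.02 against 0.272 ± 0.243 CPM. Pou2af1, a B cell transcriptional coactivator, was at 6.02 ± 9.42 against 0.293 ± 0.236 CPM. These 3 members passed adjusted over the list alone and were called by DESeq2, while over all genes their edgeR adjusted p were 0.249, 0.25 and 0.263. None passed over the list alone without vehicle replicate 2 or 3 or regressing replicate 2 or 4, and 5 passed without regressing replicate 3. Sdc1, which plasma cells share with epithelial and other cells, stood at 116 ± 57.4 CPM in regressing and 262 ± 74 CPM in vehicle tumours, the opposite direction. The list was called (adjusted p = 0.0335) when regressing replicates 1 and 4, the libraries of this group with the highest muscle scores, were left out, an alternative added after the data were seen.

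Lymphoid chemokines and B cell survival factors were called higher, with a score of 2.55 ± 0.84 (SD, n = 4) against 1.12 ± 0.14 and 7 of 8 tested members higher. Cxcl13, the chemokine that draws B cells to follicles, was at 16.4 ± 6.98 against 4.59 ± 4.09 CPM, a log2 difference of 1.84 (SE 0.76). Glycam1, a ligand for L-selectin on lymph node venules, was at 3.99 ± 4.71 against 0.0127 ± 0.0254 CPM, and Ccl21a, a chemokine of lymph nodes and lymphatic vessels, at 2.98 ± 0.409 against 0.51 ± 0.335 CPM. The latter genes were the 2 that passed adjusted over the list alone; the number was 1 without vehicle replicate 1 or 3 or regressing replicate 1, 2 or 4, and 5 without regressing replicate 3. Camera called the list (adjusted p = 0.00347; adjusted p = 0.385 with an estimated correlation), and the call was lost with the adipocyte score as a covariate (0.206). B cell markers were not called (adjusted p = 0.106), with 7 of 7 tested members higher and Cd79a, a component of the B cell receptor, at 15.3 ± 28.4 against 0.698 ± 0.532 CPM. Of its members 3 passed adjusted over the list alone, with 2 passing without regressing replicate 2, 6 and 7 without regressing replicates 1 and 3, and 0 when any other library was left out. The Cd79a mean rested on regressing replicate 4, which held 58.01 CPM of Cd79a where the other regressing tumours held 0.3993 to 1.974 CPM. The B cell list was called without regressing replicate 1 (0.0125), regressing replicate 3 (0.000664) or terminal combination replicate 4 (0.048). Regressing replicate 4 also had the highest B cell score (5.15), T cell score (4.92) and adipocyte score (5.81) of its group.

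T cell markers were called higher by camera at an adjusted p of 0.0451, with 16 of 16 members higher and a score of 2.27 ± 2.09 (SD, n = 4) against 1.18 ± 0.5 (adjusted p = 0.892 with an estimated correlation). Antigen presentation genes were called higher with 14 of 14 members higher and a score of 7.87 ± 1.18 against 7.29 ± 0.48 (adjusted p = 0.0161; adjusted p = 0.832 with an estimated correlation). Mast cell markers were called higher with 9 of 10 members higher (adjusted p = 0.0456; adjusted p = 0.832 with an estimated correlation). Cd3g, part of the T cell receptor complex, was at 15.2 ± 19 against 2.5 ± 0.79 CPM, and Psmb8, an immunoproteasome subunit, at 201 ± 102 against 103 ± 40 CPM. No member of these 3 lists passed adjusted over the list alone. All 3 calls rested on single libraries and were lost with either tissue score as a covariate. Adipocyte scores did not overlap between regressing (3.61 to 5.81) and vehicle tumours (-1.33 to 2.35). Fits of this comparison with that covariate therefore extrapolate and cannot separate it from group. With the adipocyte score T cell markers were called in the opposite direction, lower in regressing tumours (0.00118). Antigen presentation genes were lower without a call (0.256) and mast cell markers were not called (0.841). With the muscle score none was called (0.998, 0.565 and 0.34). Without regressing replicates 1 and 4 none was either (0.796, with T cell markers lower, 0.64 and 0.145). The T cell call was lost with the FFT ending, an unexplained part of some titles, as a covariate (0.0854), among libraries lacking it (0.096) and with RLE normalization (0.0528). RLE normalization also ended the mast cell call (0.0533). The T cell call was lost without vehicle replicate 1 (0.0511), 2 (0.122), 3 (0.0617) or 4 (0.0871), regressing replicate 2 (0.261) or 4 (0.89), or terminal combination replicate 1 (0.0607), 2 (0.0595) or 3 (0.0709). The antigen presentation call was lost without vehicle replicate 2 (0.139) or regressing replicate 2 (0.203) or 4 (0.515). The mast cell call was lost without vehicle replicate 2 (0.122) or 3 (0.378), regressing replicate 3 (0.0918) or 4 (0.158), or terminal combination replicate 2 (0.0577) or 3 (0.0709). Cd274, which encodes PD-L1, stood at 9.67 ± 9.5 against 6.86 ± 5 CPM (edgeR adjusted p = 0.802).

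Genes of the dividing cell were called lower. In the G2 and mitosis list 20 of 20 members were lower (camera adjusted p = 1.37e-09; adjusted p = 0.542 with an estimated correlation), and in the list of E2F targets, the genes switched on at the G1 to S transition, 20 of 21 were lower (5.75e-06; adjusted p = 0.591 with an estimated correlation). Mki67 (ENSMUSG00000031004, chromosome 7, 135689784 to 135716361), which encodes the proliferation antigen Ki-67, was at 44.1 ± 14.7 CPM (SD, n = 4) in regressing and 123 ± 48.2 CPM in vehicle tumours, a log2 difference of -1.48 (SE 0.4). Cenpf and Cenpe, kinetochore genes, were at 16.7 ± 5.62 against 44.5 ± 12.9 CPM and 16.5 ± 7.58 against 46.2 ± 12.3 CPM. Mcm4, part of the replicative helicase, was at 67.7 ± 17 against 109 ± 12.9 CPM, and Ccna2, cyclin A2, at 68.7 ± 32.9 against 133 ± 17.7 CPM. No member of either list passed adjusted over the list alone, while DESeq2 called Mki67 and Cenpf. Mitosis scores were lowest in regressing replicates 1 (4.57) and 4 (4.87), the tumours with muscle scores of 11.17 and 11.21, and stood at 6.01 and 5.51 in replicates 2 and 3, whose muscle scores were 7.71 and 9.29. The E2F call was lost (adjusted p = 0.511) when replicates 1 and 4 were both left out, while the mitosis call at a preset correlation held. With the muscle score as a covariate the mitosis list was at an adjusted p of 0.0712 and the E2F list at 0.998, where the mean member difference of the E2F list was -0.01. With the adipocyte score as a covariate both calls were lost as well, with mean member differences of 0.09 for mitosis (0.679) and 0.17 for E2F targets (0.298). That score did not overlap between the groups, so its part cannot be separated from that of group.

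Genes of other tissues were called higher in the regressing tumours too. The share of mitochondrial reads, which both muscle tissue and damaged cells raise, was 1.49% ± 0.656 (SD, n = 4) in regressing, 1.08% ± 0.334 in terminal combination and 0.731% ± 0.182 in vehicle tumours. It was highest in regressing replicates 4 (2.14%, 95% Wilson interval 2.13 to 2.15) and 1 (1.95%, 1.95 to 1.96) and terminal combination replicate 2 (1.49%, 1.48 to 1.49), the libraries with the highest muscle scores of all 12. Skeletal muscle genes were called higher, with 14 of 14 members higher (camera adjusted p = 1.82e-09; adjusted p = 0.409 with an estimated correlation), among them Atp2a1, the calcium pump of fast muscle fibres, at 6030 ± 6000 (SD, n = 4) against 451 ± 504 CPM, and Pvalb, which encodes parvalbumin, at 1010 ± 919 against 40.9 ± 47.7 CPM. Adipocyte genes were called higher, with 10 of 10 members higher (4.98e-09; adjusted p = 0.385 with an estimated correlation), among them Adipoq, the hormone adiponectin, at 22.9 ± 10.8 against 1.29 ± 1.28 CPM, Plin4 at 27.2 ± 15.1 against 1.42 ± 1.51 CPM and Car3 at 584 ± 742 against 40.1 ± 38.2 CPM. Red blood cell genes were called higher, with 6 of 6 tested members higher (0.00125; adjusted p = 0.542 with an estimated correlation), with Alas2, an enzyme of haem synthesis, at 24.2 ± 27.5 against 3.67 ± 2.84 CPM and the beta globin gene Hbb-bs at 372 ± 374 against 65.9 ± 58.9 CPM, although reads of the paired globin genes may have been shared. Adjusted over the list alone, 9 muscle, 9 adipocyte and 5 red blood cell genes passed. The muscle number was 0 without vehicle replicate 2, 3 or 4 or regressing replicate 1 or 4, the adipocyte number was 2 without regressing replicate 4, and the red blood cell number was 0 without vehicle replicate 1 or 3 or regressing replicate 2. Red blood cell genes were not called (0.0637) among the libraries whose titles lack the ending FFT, and muscle genes were not called (0.326) with the adipocyte score as a covariate.

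Schwann lineage genes were called higher as a list, with a score of 3.39 ± 0.2 (SD, n = 4) against 2.5 ± 0.41 and 9 of 13 tested members higher (camera adjusted p = 0.0456; adjusted p = 0.464 with an estimated correlation). Its members went both ways. Sox10, a Schwann cell and neural crest transcription factor, was at 0.926 ± 0.282 against 0.0341 ± 0.0418 CPM, and the myelin gene Mbp was at 23.7 ± 12.2 against 8.44 ± 2.84 CPM. The adhesion gene Ncam1 was at 36.6 ± 11.2 against 120 ± 75.4 CPM. Adjusted over the list alone, 4 members passed higher and 2 lower, 6 in all; the number was 0 without vehicle replicate 3, 3 without regressing replicate 1 and 2 without regressing replicate 2. The call was lost without vehicle replicate 1 (0.0724), 2 (0.0583) or 3 (0.169), regressing replicate 2 (0.111) or 3 (0.0687), or terminal combination replicate 2 (0.0633) or 3 (0.0552). It was also lost with RLE normalization (0.0528), among libraries lacking the FFT ending (0.0682), and with the FFT ending (0.0758), the muscle score (0.167) or the adipocyte score (0.666) as a covariate.

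The lists of CDK4/6-RB pathway components and MEK-ERK output genes were not called, unlike the E2F targets above, which were called lower at a preset correlation. The component list holds cyclins and kinases together with cell cycle inhibitors, so a directional test can miss changes in it. CDK4/6-RB pathway components had a score of 5.68 ± 0.14 (SD, n = 4) against 5.75 ± 0.19 (camera adjusted p = 0.394) and MEK-ERK output genes, the transcriptional read-out of ERK, 5.77 ± 0.4 against 5.93 ± 0.43 (0.493). Cdk4 was at 332 ± 53.5 against 430 ± 64.6 CPM, Cdk6 at 68.2 ± 8.11 against 59 ± 7.51, Ccnd1, cyclin D1, at 992 ± 326 against 663 ± 271, and Rb1 at 17.4 ± 5.45 against 16.2 ± 6.23. Map2k1 and Map2k2, which encode MEK1 and MEK2, were at 79.9 ± 9.8 against 84 ± 18.6 CPM and 188 ± 26.4 against 163 ± 18.4 CPM. The ERK targets Dusp6, Spry4 and Etv4 were at 104 ± 24.3 against 146 ± 25.3, 60.9 ± 15.4 against 53.7 ± 38.5 and 63.6 ± 50.5 against 69.9 ± 18.8 CPM. EdgeR adjusted p for these 9 genes ran from 0.515 for Cdk4 to 0.94 for Etv4. The 5 genes with the smallest edgeR p, none of which passed, were Naglu at 96.8 ± 12.7 against 49.3 ± 8.66 CPM, Bmp6 at 6.42 ± 1.58 against 1.9 ± 0.372, Iglc2 above, Bcl9 at 22.5 ± 2.87 against 44.4 ± 9.91, and Myoc at 8.88 ± 7 against 0.411 ± 0.386 (adjusted p = 0.247 for each). Groups did not overlap for 548 genes higher and 647 lower in regressing tumours, 7.64% of those tested, where chance gives 2.86%.

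**Figure D1:**
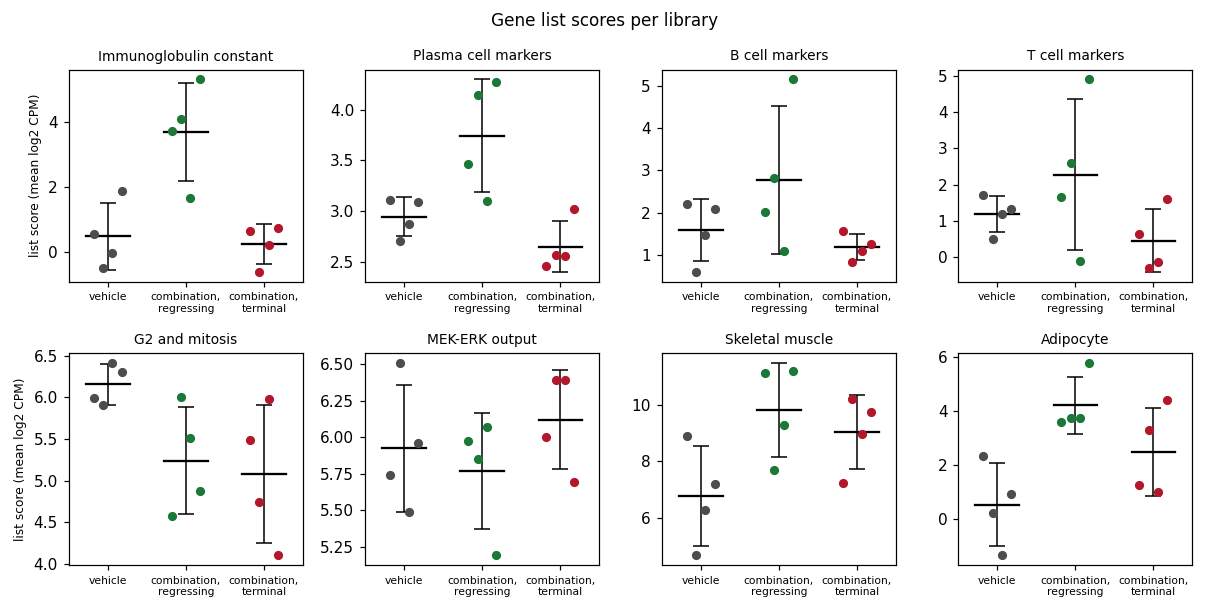
Mean log2 CPM score of 8 gene lists in each library (points), with the group mean (line) and SD (bars) for 4 vehicle, 4 regressing and 4 terminal combination tumours. The immunoglobulin scores of regressing tumours ran from 1.66 to 5.3, above the terminal combination scores of -0.63 to 0.73.

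The second comparison, terminal combination against vehicle tumours at the same harvest stage, asks how tumours that had reached the terminal point on treatment differ from untreated ones. By camera at a preset correlation, mitosis genes and E2F targets were lower, skeletal muscle, red blood cell and adipocyte genes were higher, and immunoglobulin genes were not called. None of these 5 calls held with an estimated correlation (adjusted p = 0.385, 0.409, 0.409, 0.385 and 0.563). The mitosis score was 5.08 ± 0.83 (SD, n = 4) in terminal combination and 6.16 ± 0.25 in vehicle tumours, and the immunoglobulin score 0.24 ± 0.62 against 0.47 ± 1.02 (camera adjusted p = 0.671). No gene passed in edgeR, with 925 genes at an unadjusted p under 0.05 against 782 expected by chance, and DESeq2 called 14 genes, 9 higher and 5 lower.

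G2 and mitosis genes were called lower, with 20 of 20 members lower (camera adjusted p = 6.57e-18; adjusted p = 0.385 with an estimated correlation) and so were E2F targets, with 20 of 21 members lower (6.64e-12; adjusted p = 0.409 with an estimated correlation). Mki67 was at 48.3 ± 23.3 CPM (SD, n = 4) against 123 ± 48.2 CPM, a log2 difference of -1.35 (SE 0.4; edgeR adjusted p = 0.831). Nusap1 and Bub1b, genes of the mitotic spindle and its checkpoint, were at 13.4 ± 6.1 against 27.4 ± 7.58 CPM and 52 ± 27.9 against 97.7 ± 9.33 CPM. Rrm2, an enzyme of nucleotide synthesis, was at 40.2 ± 17 against 100 ± 44.2 CPM, and Pcna, the DNA polymerase clamp, at 88.8 ± 14.1 against 138 ± 19.7 CPM. No member passed adjusted over the list alone. Mitosis scores in terminal combination replicates 1 to 4 were 5.49, 4.74, 5.98 and 4.1, beside muscle scores of 7.22, 10.23, 8.97 and 9.75. Both lists were called with each library left out in turn and with the muscle score as a covariate (adjusted p = 2.82e-06 for mitosis and 0.00404 for E2F targets). In the drugged pathways, CDK4/6-RB components were not called (0.911), with Ccnd1 at 1120 ± 405 against 663 ± 271 CPM, Ccnd2, cyclin D2, at 242 ± 45.7 against 108 ± 62.8, Cdk6 at 85.8 ± 32.6 against 59 ± 7.51 and Cdkn2c, the inhibitor p18, at 31.7 ± 11.9 against 55.7 ± 11.1, none passing over the list alone.

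Skeletal muscle genes were called higher, with 13 of 14 members higher (camera adjusted p = 7.23e-09; adjusted p = 0.409 with an estimated correlation), with Atp2a1 at 3170 ± 2790 (SD, n = 4) against 451 ± 504 CPM and Myh4, a fast myosin heavy chain, at 2920 ± 3130 against 329 ± 427 CPM. Red blood cell genes were called higher, with 6 of 6 members higher (1.09e-05; adjusted p = 0.385 with an estimated correlation), with Alas2 at 19.2 ± 14.6 against 3.67 ± 2.84 CPM and Hbb-bs at 266 ± 135 against 65.9 ± 58.9. Adipocyte genes were called higher, with 10 of 10 members higher (7.09e-05; adjusted p = 0.563 with an estimated correlation), with Plin4 at 9.91 ± 7.48 against 1.42 ± 1.51 CPM and Car3 at 232 ± 154 against 40.1 ± 38.2. Schwann lineage genes were called higher, with 9 of 13 members higher (0.0348; adjusted p = 0.409 with an estimated correlation), with S100b at 5.72 ± 2.7 against 0.997 ± 1.42 CPM and Sox10 at 0.818 ± 0.905 against 0.0341 ± 0.0418. No member of these 4 lists passed over all genes or adjusted over the list alone. The Schwann call was lost without vehicle replicate 3 (0.0783) or terminal combination replicate 3 (0.0836) and with the FFT ending (0.0666), the muscle score (0.109) or the adipocyte score (0.279) as a covariate.

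Receptor tyrosine kinases and their ligands were called higher, with 15 of 18 tested members higher and a score of 5.56 ± 0.2 (SD, n = 4) against 5.22 ± 0.31 (camera adjusted p = 0.0348; adjusted p = 0.385 with an estimated correlation). Fgf2, a fibroblast growth factor, was at 36.1 ± 23.3 against 13.7 ± 6.75 CPM. This call was lost without vehicle replicate 1 (0.0724), 3 (0.139) or 4 (0.09), regressing replicate 2 (0.0516), or terminal combination replicate 2 (0.0683) or 4 (0.0891). It was lost too without regressing replicates 1 and 4 (0.065), and with the muscle (0.052) or adipocyte score (0.247) as a covariate. MEK-ERK output genes were not called (0.0777), with 11 of 18 members higher, Dusp6 at 178 ± 113 against 146 ± 25.3 CPM, Spry4 at 73.6 ± 31.7 against 53.7 ± 38.5 and Etv4 at 68.6 ± 39.7 against 69.9 ± 18.8. That list was called higher without vehicle replicate 2 (0.0031) or terminal combination replicate 4 (0.00454), and at 0.0156 among libraries lacking the FFT ending. Interferon response genes were called lower, with 18 of 18 members lower (0.0115; adjusted p = 0.869 with an estimated correlation), with Rsad2 at 16.7 ± 9.73 against 47.4 ± 44.4 CPM and Usp18 at 15.1 ± 9.33 against 39.9 ± 37.7. No receptor, MEK-ERK or interferon gene passed adjusted over its list alone. The interferon call was lost without vehicle replicate 1 (0.497) or terminal combination replicate 2 (0.315), and among libraries lacking the FFT ending (0.114).

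Plasma cell markers were not called (camera adjusted p = 0.345), with Jchain at 1.51 ± 1.59 CPM (SD, n = 4) in terminal combination and 3.28 ± 4.33 in vehicle tumours. Igkc was at 13.5 ± 6.87 against 25.3 ± 37.7 CPM and Ighm at 37.7 ± 16.2 against 68.5 ± 37.9, while Ighg1 was at 2.33 ± 2.89 against 0.128 ± 0.131 and was the 1 immunoglobulin gene to pass adjusted over the list alone. It held 6.6 CPM in terminal combination replicate 3, and no immunoglobulin gene passed without vehicle replicate 2, 3 or 4, regressing replicate 1 or terminal combination replicate 3. All immunoglobulin genes, constant and variable, took 0.00668% ± 0.00206 of reads in the terminal combination tumours (exact two-sided permutation p = 0.4 against vehicle). Cxcl13 was at 3.46 ± 2.57 against 4.59 ± 4.09 CPM and Cd274 at 3.96 ± 1.88 against 6.86 ± 5 (edgeR adjusted p = 0.955 and 0.916). The 5 genes with the smallest edgeR p, none passing, were H2afx, a histone of the DNA damage response, at 30.4 ± 4.7 against 67.5 ± 15.4 CPM, Rmi2 at 0.86 ± 0.271 against 2.81 ± 0.376, Tmem40 at 0.406 ± 0.188 against 2.07 ± 0.755, Fam32a at 97.3 ± 12.6 against 50.9 ± 5.97 and Cdk5rap1 at 7.38 ± 1.28 against 19.1 ± 6.05 (adjusted p = 0.831 for each). Groups did not overlap for 189 genes higher and 203 lower, 2.5% of those tested, where chance gives 2.86%.

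**Figure D2:**
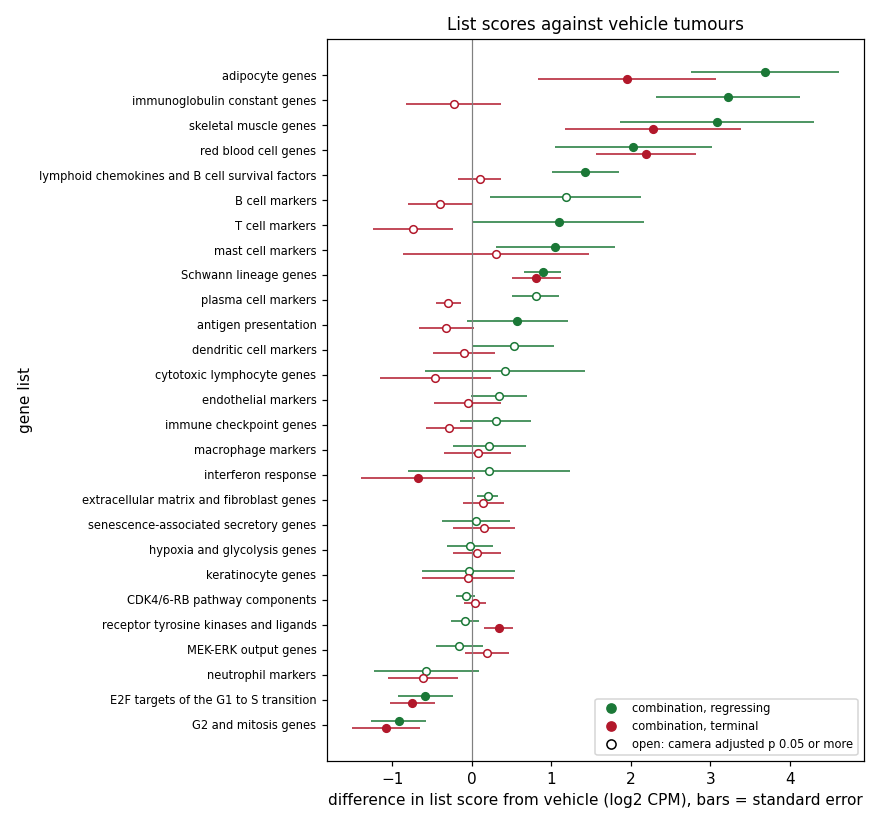
Difference in list score (log2 CPM) from vehicle tumours for 27 gene lists, regressing tumours in green and terminal combination tumours in red, 4 libraries per group, bars showing the standard error. Filled points mark lists called by camera at a preset correlation; immunoglobulin constant genes were called in regressing (adjusted p = 5.93e-08; 0.385 with an estimated correlation) and not in terminal combination tumours (0.671). With an estimated correlation 0 of the 27 lists were called in each comparison.

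The third comparison sets terminal combination against regressing tumours, both on treatment, and asks what differs between tumours at the terminal point and tumours shrinking under the same drugs. Antibody genes had the largest score difference of the 27 lists. The immunoglobulin score was 0.24 ± 0.62 (SD, n = 4) in terminal combination and 3.69 ± 1.51 in regressing tumours, and every regressing tumour lay above every terminal combination tumour. By camera at a preset correlation, T cell, B cell, plasma cell and lymphoid chemokine genes were lower as well, while MEK-ERK output genes and receptor tyrosine kinases with their ligands were higher. None of these 6 calls held with an estimated correlation (adjusted p = 0.591, 0.567, 0.385, 0.385, 0.563 and 0.385), and the MEK-ERK call held in 9 of 12 fits with a library left out. No gene passed in edgeR, with 1090 at an unadjusted p under 0.05 against 782 expected by chance, and DESeq2 called 51 genes, 24 higher and 27 lower. Without terminal combination replicate 4, 1 gene passed, Pcsk6 at a log2 difference of -2.32 (adjusted p = 0.00999), named here after its value was seen. The library left out had the highest Pcsk6 of its group, at a log2 CPM of 5.59 against 2.44 to 2.66 in the others.

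Immunoglobulin constant genes were called lower, with 10 of 10 members lower (camera adjusted p = 1.67e-11; adjusted p = 0.385 with an estimated correlation), and 9 passed adjusted over the list alone, with 8 to 11 passing when any single library was left out. The log2 difference was -5.24 (SE 1.15) for Igkc and -3.57 (SE 0.67) for Ighm, with edgeR adjusted p of 0.705 and 0.531. The share of reads from all immunoglobulin genes was lower by 14.7-fold as a ratio of geometric means (exact two-sided permutation p = 0.0286, the smallest that 4 against 4 can give; adjusted p = 0.0856). Plasma cell markers were called lower, with a score of 2.65 ± 0.25 (SD, n = 4) against 3.74 ± 0.56 and 11 of 14 members lower (camera adjusted p = 0.0142; adjusted p = 0.385 with an estimated correlation). Jchain, Mzb1 and Pou2af1 passed adjusted over the list alone, at 1.51 ± 1.59 against 53.4 ± 41.5, 0.129 ± 0.15 against 4.81 ± 5.02 and 0.193 ± 0.207 against 6.02 ± 9.42 CPM; the number was 2 without regressing replicate 4 or terminal combination replicate 2 and 5 without terminal combination replicate 4. The plasma cell call was lost without regressing replicate 2 (0.0909) or terminal combination replicate 3 (0.0689). DESeq2 called 11 immunoglobulin genes lower and the same 3 plasma cell markers. Of the 5 genes with the smallest edgeR p, 4 were immunoglobulin genes, namely Iglc2, Iglc1, Ighm and Igkv6-15, a kappa variable gene whose reads may be shared with its relatives, at 0.0271 ± 0.0313 against 7.46 ± 10.6 CPM. The other was Plat, tissue plasminogen activator, at 232 ± 69.3 against 78.5 ± 17.9 CPM (adjusted p = 0.531 for each).

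T cell markers were called lower, with 16 of 16 members lower (camera adjusted p = 1.4e-05; adjusted p = 0.591 with an estimated correlation), and 14 passed adjusted over the list alone. Cd5 was at 0.753 ± 0.252 (SD, n = 4) against 6.32 ± 9.04 CPM, Cd3g at 1.45 ± 1.37 against 15.2 ± 19 and Trbc1, a T cell receptor constant gene, at 0.732 ± 0.602 against 10 ± 14.9. B cell markers were called lower, with 7 of 7 members lower (0.00363; adjusted p = 0.567 with an estimated correlation), 3 of them adjusted over the list alone, with Cd79a at 0.327 ± 0.444 against 15.3 ± 28.4 CPM and Spib, a transcription factor of B cells, at 0.916 ± 0.357 against 13 ± 23.4. Lymphoid chemokines and B cell survival factors were called lower, with 7 of 8 members lower (0.000415; adjusted p = 0.385 with an estimated correlation), 5 of them adjusted over the list alone, with Cxcl13 at 3.46 ± 2.57 against 16.4 ± 6.98 CPM, Ltb, lymphotoxin beta, at 1.77 ± 0.824 against 18.6 ± 28.9 and Cxcl12 at 278 ± 111 against 567 ± 215. The scores of regressing replicates 1 to 4 were 1.66, 2.6, -0.11 and 4.92 for T cells and 2.02, 2.82, 1.08 and 5.15 for B cells. Without regressing replicate 4, or without terminal combination replicate 1 or 2, no T cell, B cell or lymphoid chemokine gene passed over the list alone. Without terminal combination replicate 3 the numbers were 0, 0 and 1. Without regressing replicate 1 the lymphoid chemokine number was 3. The B cell number was 0 without terminal combination replicate 4, and 5 to 8 when any vehicle library or regressing replicate 1 or 3 was left out. With the adipocyte score as a covariate the T cell list was at an adjusted p of 0.0701 and the B cell list at 0.168.

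Antigen presentation genes were called lower, with 14 of 14 members lower (camera adjusted p = 1.33e-05; adjusted p = 0.563 with an estimated correlation), with Psmb8 at 83 ± 38 (SD, n = 4) against 201 ± 102 CPM; the call was lost without regressing replicates 1 and 4 (0.065) and with the adipocyte score as a covariate (0.0565). Interferon response genes were called lower, with 18 of 18 members lower (0.00329; adjusted p = 0.832 with an estimated correlation), with Cxcl9, a chemokine induced by interferon gamma, at 14.1 ± 11.8 against 99.3 ± 125 CPM. This call was lost without regressing replicate 2 (0.177) or 4 (0.542) or terminal combination replicate 2 (0.181). It was lost too without regressing replicates 1 and 4 together (0.366) and with the adipocyte score as a covariate (0.181). Immune checkpoint genes were called lower, with 9 of 11 members lower (0.0166; adjusted p = 0.585 with an estimated correlation), with Btla, an inhibitory lymphocyte receptor, at 1.21 ± 0.416 against 6.18 ± 6.85 CPM and Cd274 at 3.96 ± 1.88 against 9.67 ± 9.5. Btla was the 1 checkpoint gene to pass adjusted over the list alone, and none passed when any vehicle library, any terminal combination library or regressing replicate 4 was left out, while 2 passed without regressing replicate 3. The checkpoint call was lost without regressing replicate 2 (0.125) or 4 (0.0695) or terminal combination replicate 3 (0.155), and with the muscle (0.0523) or adipocyte score (0.238) as a covariate. Endothelial markers were called lower, with 11 of 12 members lower (0.00942; adjusted p = 0.759 with an estimated correlation), a call lost without terminal combination replicate 3 (0.443), without regressing replicates 1 and 4 (0.126) and with the adipocyte score as a covariate (0.125). Dendritic cell markers were called lower, with 9 of 12 members lower (0.0451; adjusted p = 0.832 with an estimated correlation), a call lost without vehicle replicate 1 (0.0664), 2 (0.0544), 3 (0.0701) or 4 (0.0667), regressing replicate 1 (0.0512), 2 (0.0909) or 4 (0.353), or terminal combination replicate 1 (0.302) or 3 (0.448). It was also lost with the FFT ending as a covariate (0.0534), among libraries lacking that ending (0.396), without regressing replicates 1 and 4 (0.787) and with the muscle (0.231) or adipocyte score (0.596) as a covariate. Of the antigen presentation, interferon, endothelial, dendritic and mast cell genes, none passed adjusted over its list alone. Mast cell markers were called lower (0.0451; adjusted p = 0.832 with an estimated correlation) although 5 of 10 members were higher and the mean member difference was 0.02. That call was lost without vehicle replicate 4 (0.0597), regressing replicate 3 (0.108) or 4 (0.216), or terminal combination replicate 3 (0.655) or 4 (0.64). It ended as well with the FFT ending (0.287), the muscle score (0.0587) or the adipocyte score (0.183) as a covariate, and without regressing replicates 1 and 4 (0.256).

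MEK-ERK output genes were called higher, with 16 of 18 members higher and a score of 6.12 ± 0.34 (SD, n = 4) against 5.77 ± 0.4 (camera adjusted p = 0.0072; adjusted p = 0.563 with an estimated correlation). Dusp6, the ERK phosphatase, was at 178 ± 113 against 104 ± 24.3 CPM and the receptor gene Epha2 at 76.1 ± 15.9 against 44.5 ± 21.7. This call was lost without regressing replicate 4 (0.115) or terminal combination replicate 2 (0.0778) or 3 (0.0689), without regressing replicates 1 and 4 (0.198), and with the adipocyte score as a covariate (0.197). Receptor tyrosine kinases and their ligands were called higher, with 15 of 18 members higher and a score of 5.56 ± 0.2 against 5.14 ± 0.17 (0.0144; adjusted p = 0.385 with an estimated correlation). Igf1r, the insulin-like growth factor receptor, was at 70.4 ± 15.3 against 38.1 ± 7.78 CPM, Hgf, hepatocyte growth factor, at 37.6 ± 13.9 against 18 ± 7.76 and Fgf2 at 36.1 ± 23.3 against 14.3 ± 4.52. No MEK-ERK or receptor gene passed adjusted over its list alone. The receptor call held with each library left out in turn and was lost without regressing replicates 1 and 4 (0.14). Mki67 was at 48.3 ± 23.3 against 44.1 ± 14.7 CPM, and neither G2 and mitosis genes (0.291) nor E2F targets (0.266) were called. Mitosis genes were called lower without regressing replicate 1 (0.000893) or terminal combination replicate 3 (0.000347), and E2F targets without regressing replicate 1 (0.000727) or 4 (0.0161) or terminal combination replicate 3 (0.00556). Both were lower among libraries lacking the FFT ending (0.000277 and 0.000916) and without regressing replicates 1 and 4 (8.87e-08 and 5.78e-11).

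Adipocyte genes were called lower, with 9 of 10 members lower in terminal combination than in regressing tumours (camera adjusted p = 2.81e-06; adjusted p = 0.464 with an estimated correlation), with Adipoq at 5.55 ± 5.59 (SD, n = 4) against 22.9 ± 10.8 CPM and Cfd, the fat-derived complement factor adipsin, at 17.3 ± 14.2 against 111 ± 110. No adipocyte gene passed adjusted over the list alone. Skeletal muscle genes were not called (0.0623), with 14 of 14 members lower, but were called without vehicle replicate 2 (0.0472), regressing replicate 2 (0.000712) or terminal combination replicate 2 (0.00459) or 4 (0.027). Red blood cell genes were not called (0.729) except without regressing replicate 2 (0.0219). Groups did not overlap for 375 genes higher and 236 lower, 3.9% of those tested, where chance gives 2.86%. A test of all 3 groups together found no gene in edgeR (1451 at an unadjusted p under 0.05) and 262 genes in the DESeq2 likelihood ratio test; without terminal combination replicate 4, edgeR found 1.

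**Figure D3:**
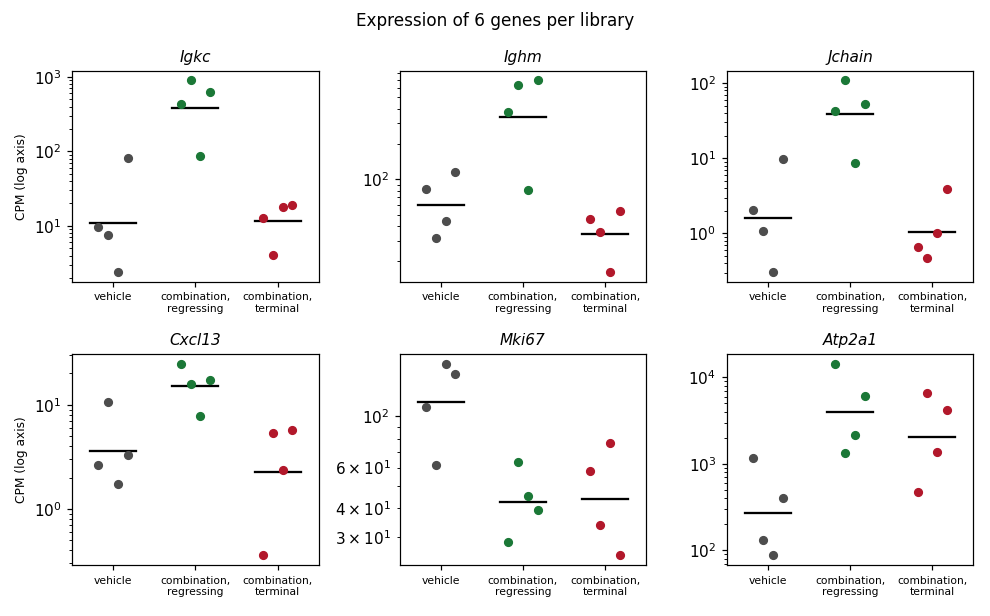
CPM on a log axis in each library (points) for Igkc, Ighm, Jchain, Cxcl13, Mki67 and Atp2a1, with the geometric mean of each group of 4 (line). Igkc ranged from 87.84 to 900.2 CPM in regressing tumours and from 4.11 to 19.05 CPM in terminal combination tumours.

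The remaining lists were not called with all 12 libraries. For regressing against vehicle the camera adjusted p was 0.92 for cytotoxic lymphocyte genes, 0.423 for macrophage markers, 0.209 for dendritic cell markers, 0.423 for neutrophil markers, 0.744 for interferon response, 0.462 for checkpoint genes, 0.91 for senescence-associated secretory genes, 0.78 for receptor tyrosine kinases and ligands, 0.377 for extracellular matrix and fibroblast genes, 0.0777 for endothelial markers, 0.911 for keratinocyte genes and 0.793 for hypoxia and glycolysis genes. For terminal combination against vehicle it was 0.377 for B cell markers, 0.0656 for T cell markers, 0.266 for cytotoxic genes, 0.928 for macrophage, 0.738 for dendritic cell, 0.377 for neutrophil and 0.747 for mast cell markers, 0.207 for antigen presentation, 0.91 for lymphoid chemokines, 0.185 for checkpoint, 0.53 for secretory, 0.671 for matrix, 0.689 for endothelial, 0.851 for keratinocyte and 0.71 for hypoxia genes. Between the treated groups it was 0.212 for cytotoxic, 0.394 for macrophage, 0.988 for neutrophil, 0.325 for CDK4/6-RB, 0.689 for secretory, 0.671 for Schwann, 0.537 for matrix, 0.988 for keratinocyte and 0.538 for hypoxia genes. The sign of the test, mean or median differed for secretory genes in the first comparison, for macrophage, lymphoid chemokine, CDK4/6-RB and hypoxia genes in the second, and for neutrophil, mast cell, Schwann, matrix and red blood cell genes in the third. Leaving out 1 library made calls in some of these lists. For regressing against vehicle they were cytotoxic (0.00237), dendritic cell (0.00382) and interferon genes (0.00719) without regressing replicate 3, macrophage markers (0.00764) without vehicle replicate 1, and endothelial markers without vehicle replicate 3 (0.00347) or 4 (0.0112) or terminal combination replicate 4 (0.0414). For terminal combination against vehicle they were T cell markers without regressing replicate 3 (0.0138) or 4 (0.00473) or terminal combination replicate 4 (0.00761), antigen presentation without vehicle replicate 2 (0.0435) or terminal combination replicate 4 (0.0135), checkpoint genes without the same libraries (0.0296 and 0.0497), cytotoxic genes without terminal combination replicate 4 (0.00939), endothelial markers without vehicle replicate 2 (0.018), hypoxia genes without vehicle replicate 3 (0.0102) and macrophage markers without vehicle replicate 1 (0.0438). Between the treated groups they were cytotoxic genes without regressing replicate 3 (1.82e-06) or terminal combination replicate 4 (0.0135).

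The changes of both treated groups from vehicle were correlated. Across the 15650 genes tested the log2 differences of regressing and terminal combination tumours from the shared vehicle tumours correlated at r = 0.659, and 69.5% of genes had the same sign in both; genes are not independent replicates. Sharing the vehicle libraries alone gave r of 0.499 in 100 simulations (0.474 to 0.522) and the same sign in 66.6% of genes (65.5 to 67.5). Genes were drawn independently in these simulations, so both ranges leave out the correlation between genes. They cannot decide whether the treated groups share a response. When each treated group was set against 2 separate vehicle tumours, r was 0.046 to 0.292 and the same sign was seen in 53.5% to 57.3% of genes over the 6 ways.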

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

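Every test of an explanation in this part was chosen after the result it measures had been seen, as were the splits of the pairs of groups; the splits of all 3 groups were planned before.

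Immunoglobulin constant genes were higher in regressing than in terminal combination tumours by 3.45 (SE 0.788) in list score on the log2 scale. Adjoining muscle or fat is argued against as the whole cause, as far as the tissue scores measure it in a linear fit. The difference was 2.98 (SE 0.902) with the adipocyte score as a covariate, which lowered it more than the muscle score did (3.31). Without the libraries whose titles end in FFT the difference was 3.58 (SE 1.14). Since 1 regressing and 1 terminal combination library carry that ending, leaving them out could hardly remove the difference and does not test their handling. Lymph node tissue may be present in regressing replicate 4, where 22 of 23 detected B and T cell markers had their highest value and Ighd had 857 counts against 8 to 15 in the other regressing tumours. In regressing replicates 1 to 3 the immunoglobulin difference was 2.92 (SE 0.816, exact permutation p = 0.0286) and the B cell marker difference 0.79 (SE 0.528, exact permutation p = 0.2), and lymph node tissue and antibody-making cells within the tumours cannot be told apart there. The bound for little lymph node tissue was 0.5 of the immunoglobulin difference, 1.46, and the B cell difference plus 2 SE, 1.85, lies above it. This rests on the width chosen: the test first used 1 SE, which gives 1.32 and would have argued against lymph node tissue, and the width was changed after the value was seen. A response of the host during regression, which the design names through the harvest label, stays open and was not tested.

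Skeletal muscle genes were higher in treated than in vehicle tumours by 2.68 in list score. A lower share of tumour cells that raises every other cell type alike is argued against, since the muscle score difference exceeded the mean difference of macrophage, endothelial and fibroblast scores, 0.155, by 2.53 (SE 0.87). The test covers only a rise alike across those lists. Adipocyte and red blood cell scores, left out of it, rose by 3.69 and 2.034 in regressing and by 1.951 and 2.195 in terminal combination tumours. Pieces of host muscle in the samples may account for it, and within groups the muscle genes moved together with a median pairwise r of 0.78. That does not tell host muscle from a change in expression, since other lists moved together as much. In regressing against vehicle tumours the estimated correlation was 0.72 for muscle and 0.856 for mitosis genes. A change within muscle or tumour cells under treatment stays open and was not tested.

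G2 and mitosis genes were lower in both treated groups. With the muscle score as a covariate the score difference from vehicle went from -0.92 (SE 0.44) to -0.26 (SE 0.525) in regressing and from -1.08 (SE 0.44) to -0.59 (SE 0.468) in terminal combination tumours, with a slope on muscle of -0.215 (SE 0.114). Dilution of the tumour RNA by muscle and an effect of the drugs on division cannot be told apart in either group, because muscle scores differ between the groups and both differences lie within 2 SE of 0 after the correction. With the adipocyte score as the covariate instead, the differences were 0.144 (SE 0.551) and -0.516 (SE 0.416), with a slope of -0.288 (SE 0.115). The value for regressing tumours is an extrapolation, since their adipocyte scores did not overlap those of vehicle tumours. Camera weighs the list against other genes at a preset correlation. With the muscle score as the covariate its call ended in regressing tumours (adjusted p = 0.0712) and not in terminal combination tumours (2.82e-06).

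Other groupings of the same libraries show how often chance gives a result as large. For regressing against vehicle tumours, edgeR gave 1986 genes at an unadjusted p, with 1779 the highest of the other splits. DESeq2 gave 483, with 385 the highest. Each count was reached by 1 of 35 splits, the real one, which is the smallest share that 35 splits can give. These splits were chosen after the data were seen and several counts were examined without adjustment, so chance is not excluded for either. The split with 385 genes set vehicle replicate 1 and regressing replicates 1, 3 and 4, the highest muscle scores of these 8 libraries, against the rest. It differs from the real split only by the exchange of vehicle replicate 1 and regressing replicate 2. The split with 291 genes set vehicle replicate 1 and regressing replicates 1, 2 and 4 against the rest and did not follow the muscle scores. Muscle and treatment therefore cannot be told apart as the source of these counts. Chance cannot be excluded for the 11 lists called (17 of 35; highest 17). For terminal combination against vehicle tumours chance cannot be excluded for the 925 genes at an unadjusted p (14 of 35; highest 2586), the 14 genes of DESeq2 (24 of 35; highest 747) or the 8 lists (11 of 35; highest 14). Between the treated groups it cannot be excluded for the 1090 genes at an unadjusted p (8 of 35; highest 2579), the 51 genes of DESeq2 (7 of 35; highest 917) or the 15 lists (6 of 35; highest 17), where lists were adjusted within the comparison and so number 15, not 14. The split with 917 genes set regressing replicates 1 and 4 and terminal combination replicates 2 and 4, the tumours richest in muscle, against the rest, which points to a structure of the samples other than their groups. For all 3 groups, the 1451 genes at an unadjusted p were reached in 13 of 100 splits (highest 2412), so chance cannot be excluded. For the 0 genes at an adjusted p the splits decide nothing, since every split gives at least 0: all 35 of 35 in each comparison (highest 0, 2 and 51) and 100 of 100 for all 3 groups (highest 95).

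Single libraries stood apart from the other 3 of their group in 17 of 369 groups of values, where about 18.4 would be expected by chance. Vehicle replicate 3 had a secretory gene score of 6.1 against 4.57 to 4.77 and a hypoxia and glycolysis score of 6.89 against 5.77 to 5.83. Regressing replicate 4 had an adipocyte score of 5.81 against 3.61 to 3.76 and a log2 CPM of Rb1 of 4.68 against 3.85 to 3.94. Terminal combination replicate 1 had a log2 CPM of Naglu of 5.73 against 6.09 to 6.16, and replicate 2 of that group had Igf1r at 6.54 against 5.93 to 6.02. Vehicle replicate 1 had Plat at 7.93 against 7.1 to 7.22, vehicle replicate 4 had Epha2 at 6.36 against 5.49 to 5.63, and vehicle replicate 3 had Glycam1 at -2.63 against -3.18 in each of the others, which is 1 count against 0. Among genes chosen after their values were seen, regressing replicate 4 had Npas2 at -1.92 against 0.97 to 1.08 and Ighd at 6.05 against -0.8 to 0.09, and terminal combination replicate 4 had Pcsk6 at 5.59 against 2.44 to 2.66. Vehicle replicate 4 had Per3 at 2.07 against 1.35 to 1.47 and Igkv3-2 at 4 against -3.18 in each of the others, and terminal combination replicate 3 had Igkv3-2 at 1.21 against -3.18 to -2.58. Vehicle replicate 2 had Ciart at -1.1 against 0.54 to 0.75, and regressing replicate 3 had Cry1 at 3.51 against 3.99 to 4.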

How the results depend on the processing

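Added after the data were seen were the alternatives that leave out regressing replicates 1 and 4 or use the muscle or adipocyte score as a covariate; all others were planned. Of 12394 alternative values of 553 results, 11945 were rated the same. A test was so rated if its direction and side of the threshold held, or if it passed in neither setting. A count was so rated if it stayed within a set ratio of its main value. In 437 of the 11945 the sign changed and neither setting passed. The cause was not tested for any change below except where a sentence gives it. In edgeR the count of genes was 0 in every contrast under RLE normalization, no filter, the FFT covariate, the libraries without FFT, the 8-library fits, the gene exclusions and the 2 score covariates. DESeq2 called 483, 14 and 51 genes in the 3 comparisons and 262 across groups; leaving out single libraries gave 0 to 1 gene for terminal combination against regressing and across groups. Depth limits genes near 0 counts, such as Glycam1 and Sox10 in vehicle tumours, since a count of 0 allows 0.133 to 0.227 CPM.

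With an estimated correlation and with fry, 0 lists were called in each comparison. The adjusted p with an estimated correlation and by fry were 0.385 and 0.185 for immunoglobulin genes in both contrasts that called them and for plasma cell markers between the treated groups. They were 0.591 and 0.518 for E2F targets and 0.542 and 0.315 for mitosis genes in regressing against vehicle, 0.409 and 0.315 and 0.385 and 0.255 for the same lists in terminal combination against vehicle, and 0.563 and 0.551 for MEK-ERK output between the treated groups. These tests allow for the correlation among a list's genes, which camera presets.

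With single libraries left out, the number of lists called was 7 to 13 for regressing against vehicle. For MEK-ERK output the adjusted p was 0.0031 to 0.527 in terminal combination against vehicle and 0.000464 to 0.115 between the treated groups. Between the treated groups it was 0.00261 to 0.0909 for plasma cell markers, 0.000727 to 0.993 for E2F targets and 0.000347 to 0.836 for mitosis genes. Among the libraries without FFT it was 0.0156 for MEK-ERK output against vehicle, and 0.000916 and 0.000277 for E2F targets and mitosis genes between the treated groups.

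Without regressing replicates 1 and 4, regressing against vehicle gave 0.0335 for plasma cell markers and 0.511 for E2F targets; the sign changed without a call for T cell markers (0.796), and the direction turned for cytotoxic genes (0.0131). Between the treated groups 9 lists were called, with MEK-ERK output at 0.198, E2F targets at 5.78e-11 and mitosis genes at 8.87e-08. With the muscle score as a covariate 4 lists were called in regressing against vehicle, with mitosis genes at 0.0712 and E2F targets at 0.998, where the mean member difference was -0.01 and only the sign given by camera, which weighs the list against other genes, changed; MEK-ERK output was at 0.00579 in terminal combination against vehicle, and E2F targets and mitosis genes at 0.00318 and 0.00789 between the treated groups. With the adipocyte score 6, 13 and 6 lists were called in the 3 comparisons. In regressing against vehicle the direction turned past the threshold for T cell markers (0.00118), cytotoxic (0.000464), dendritic cell (0.000639) and interferon genes (0.0483), and the sign of the test changed without a call for antigen presentation (0.256), E2F (0.298) and mitosis genes (0.679). Adipocyte scores did not overlap between those groups, so these values extrapolate and cannot separate the score from group. In terminal combination against vehicle immunoglobulin genes were at 0.0478 (lower) and MEK-ERK output at 0.00268. Lists lower there with the muscle and the adipocyte score, and not called without them, were B cell (0.0346 and 0.000955), T cell (0.000906 and 1.96e-08), cytotoxic (0.0494 and 9.61e-05), dendritic cell (0.0352 and 0.000464), antigen presentation (0.012 and 8.43e-05) and checkpoint genes (0.0346 and 0.00236). T cell markers were also called lower without regressing replicates 1 and 4 (0.00404), and endothelial markers lower among libraries without FFT (0.000254). Between the treated groups the sign of dendritic cell markers changed without a call (0.596), MEK-ERK output was at 0.197, E2F targets at 1.45e-05 and mitosis genes at 2.08e-06.

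The correlation of 0.659 between the contrasts that share vehicle libraries was 0.213, 0.286, 0.22, 0.13, 0.292 and 0.046 when the vehicle tumours were split 2 and 2, which removes the sharing and leaves fewer libraries. Other results, such as single named genes and the lists not in the comparisons' main questions, lost a call in 56 values with single libraries left out. They lost one in 94 values under other settings, and gained one in 28 and 63. Counts of list members moved beyond the set ratio in 74 and 54.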

Other observations

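The clock genes below were chosen after their values had been seen. Group means of core clock and clock-controlled genes in regressing tumours lay above those of vehicle tumours for some and below for others. Dbp, a clock-controlled transcription factor, was at 51.8 ± 29.8 CPM (SD, n = 4) in regressing, 7.73 ± 6.34 in vehicle and 10 ± 4.78 in terminal combination tumours, a log2 difference from vehicle of 2.75 (SE 0.62; edgeR adjusted p = 0.247). Nr1d1 and Nr1d2, repressors of Arntl, were at 79 ± 19.6 and 67.4 ± 21.2 CPM in regressing against 19.3 ± 4.06 and 24.5 ± 5.05 in vehicle and 39.8 ± 23.9 and 30.1 ± 14 in terminal combination tumours. Arntl, which encodes the activator BMAL1, was at 12 ± 1.61 CPM in regressing, 37.2 ± 27.1 in vehicle and 49.9 ± 26.9 in terminal combination tumours, a log2 difference from vehicle of -1.63 (SE 0.5). Npas2, its partner, was at 1.49 ± 0.895, 5.31 ± 2.14 and 5.01 ± 4.21 CPM. Of 14 clock genes looked at, the values of these 5 did not overlap between regressing and vehicle tumours, and none of the 14 passed in edgeR at an adjusted p under 0.05. Per3 and Tef were at 11 ± 7.51 and 128 ± 66.1 CPM in regressing against 2.95 ± 0.762 and 49.6 ± 19.5 in vehicle tumours, with overlap, and Per1, at 26.7 ± 9.78 against 56.2 ± 28.7 CPM, went the opposite way. The others also overlapped, with log2 differences from vehicle of 1.07 for Per2, 2.35 for Hlf, 0.27 for Ciart, -0.27 for Clock, -0.3 for Cry1 and -1.27 for Nfil3. The time of day of harvest is not given in the sources used here.

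The make-up of the immunoglobulin transcripts is given as values. Ighm took from 56% (95% Wilson interval 52 to 60) of heavy chain constant reads, in terminal combination replicate 3, to 91.2% (88.3 to 93.4), in vehicle replicate 2, and Ighg1 took 22.8% (19.6 to 26.4) in terminal combination replicate 3. Vehicle replicate 2 held 444 Ighm, 104 Igkc and 6 heavy chain variable counts, where regressing replicate 2 held 10945, 15504 and 936. Ighm and Igkc counts were also far apart in vehicle replicates 1 (1934 and 226) and 3 (876 and 47). The same held in terminal combination replicates 1 (891 and 246), 2 (593 and 69) and 4 (941 and 334). They were closer in vehicle replicate 4 (1974 and 1399) and terminal combination replicate 3 (331 and 372). The Ighm share in vehicle replicate 2 and the other libraries with few Igkc counts therefore need not describe whole antibody transcripts. The most abundant kappa variable gene was Igkv3-2 in vehicle replicate 4 (49.7% of kappa variable reads, 95% Wilson interval 45.6 to 53.9), regressing replicate 2 (39.3%, 38 to 40.6), regressing replicate 3 (28.7%, 25.5 to 32) and terminal combination replicate 3 (34.1%, 26.6 to 42.5). Thinned to 500 kappa variable reads, the effective number of variable genes was 10.8, 5.8, 8.3 and 11.6 in regressing replicates 1 to 4 and 3.7 in vehicle replicate 4, the libraries with enough reads. Reads of related variable genes can be shared, and whole reads over variable genes do not identify clones.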
